A study of Homo sapiens with 24 samples.

How the data were processed

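Gene expression had been measured in 12 human samples, each hybridised to a U133A and a U133B array (Affymetrix oligonucleotide arrays, on which a gene is read by 1 or more probe sets), giving 24 arrays. Per the labels, total RNA was extracted with Trizol and biotin labelled. Per the series description, marrow and blood of healthy individuals were taken in parallel, marrow stages were separated on a density gradient, and other cells were depleted with magnetic beads. The samples fall into 4 populations of 3 replicates, named PM, MY, bmPMN and pbPMN in the sample titles. The labels give MY as myeloblasts, although the abbreviation may stand for a later stage, so each comparison is written with the abbreviations. Nothing in the labels says which replicates came from which donor, and p-values therefore measure the spread between these samples, which may be partly technical.

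The deposited tables hold 1 intensity per probe set and array on a linear scale. The software, summary method, scaling and floor behind the deposited intensity values are not given in the sources used here. The U133A table has 22283 rows and the one of U133B has 22639. Between 2.54% and 8.34% of the rows of an array were listed at 1 or less. On U133A, 6 control rows had no values and were left out. The median intensity per array had a mean of 105 ± 1.99 (SD, n = 3) in PM, 82.4 ± 1.03 in MY, 60.3 ± 2.55 in bmPMN and 63.3 ± 2.65 in pbPMN on U133A. On U133B it was 50.3 ± 0.638, 57.1 ± 0.835, 46.8 ± 0.385 and 58.5 ± 0.347. The tables were therefore not scaled to a common median across populations. No measure of signal over background was used here, and the 3 replicates per population limit the precision.

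Probe sets were named through the platform annotation supplied with the tables. On U133A, 19065 rows have 1 gene symbol, 1043 have several and 2107 have none, besides 68 control rows. On U133B the numbers are 15426, 554, 6597 and 62. Symbols were looked up by Entrez number in a RefSeq gene table of assembly GRCh38.p14, which changed 0 of them, and no coordinates were taken from it. Values under the 20th percentile of a table (19.4 on U133A and 12.9 on U133B) were set to it, log2 was taken, and rows above the 40th percentile (53.3 and 38.1) on at least 3 arrays were kept. For each gene the probe set with the highest mean was used, and U133B added genes not on U133A. This left 10884 genes from U133A and 4936 from U133B.

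Each array type was fitted separately in limma (lmFit and eBayes) with all 12 arrays, 4 group means and no covariate. The tests were two-sided, with Benjamini-Hochberg adjustment within an array type and a threshold of 0.05. Where all arrays of the dimmer population lay at or under the floor, the fold is against the floor and is given as a lower bound. That population then has no spread in the fit, so the p-value does not measure the spread of its samples. Genes were named by a rule set before the data were examined, namely the 10 largest rises and 10 largest falls (5 and 5 for bmPMN against PM) among genes past the threshold whose replicates did not overlap between the populations. Members of a gene list could be named as its examples, the largest absolute change first. XIST, Y-linked genes, symbols that only number a clone or reading frame, and rows with several symbols were left out. Of 3 against 3 replicates, 10% of unchanged genes would not overlap by chance. Another 33 gene lists, 9 of them cell type markers, were fixed at the same time and tested on U133A with camera at a preset correlation of 0.01. Beside it stand camera with an estimated correlation and fry, both also on U133A alone. fry tests whether a list moved on average and does not set it against other genes. Members of a list that fry calls can move both ways.

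Whether the row names carry gene identity was examined after the tables had been seen. Probe sets listed under one gene were set against each other by rank correlation with 10000 permutations. Probe sets present on both array types, control probe sets and the intensity ranks of the gene lists were examined in the same way, the last against 10000 random lists. All cyclic shifts of 12 row orders (the table, probe set name as text and as number, symbol, accession and Entrez number, each also reversed) were scanned for agreement within genes.

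The model was tested on simulated data built from the real means and replicate spread, with MY and PM differing in 200 genes. Among 13251 simulated genes it recovered 9 of 67 genes changed 1.5-fold, 39 of 67 changed 2-fold and 55 of 66 changed 4-fold. It called 7 unchanged genes. Only 200 of the simulated genes were changed, whereas 72.3% of the genes tested were called in the real MY against PM. The adjustment is stricter where fewer genes change, so these counts do not give the share of changes recovered in the real comparisons. With a shift imposed on every member of 1 list at a time in the real MY arrays (10884 genes), camera called 6 of the 33 lists at 2-fold, 28 at 4-fold and 32 at 8-fold. The scan of row orders recovered a simulated shift in a table of 22283 rows with a correlation of 0.3 within genes.

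Alternatives covered normalization (quantile or median scaling), the floor, the filter, the choice of probe set, the samples in the fit, a replicate block, joint adjustment, an intensity trend, a minimum fold, and each replicate left out. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.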

Results

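Transcript levels were recorded in 4 granulocytic populations of healthy individuals. PM, MY and bmPMN were isolated from bone marrow and pbPMN, the neutrophils, from peripheral blood. Each population had 3 replicates, and each replicate was read on a U133A and a U133B array. The series concerns terminal granulocytic differentiation, and the comparisons were MY against PM, bmPMN against MY, pbPMN against bmPMN, and bmPMN against PM. The label of MY, myeloblasts, would place MY before PM if PM stands for promyelocytes, so no order of these populations is implied.

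Replicates of a population ranked the probe sets alike. Spearman correlations over probe sets, which are not independent replicates, lay between 0.965 and 0.985 in the 12 pairs within populations on U133A and between 0.959 and 0.983 on U133B. Between populations they were far lower, from 0.306 to 0.463 over 54 pairs on U133A and from 0.380 to 0.487 on U133B. The highest mean between populations was that of bmPMN and pbPMN, 0.458 on U133A and 0.482 on U133B.

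**Figure D1:**
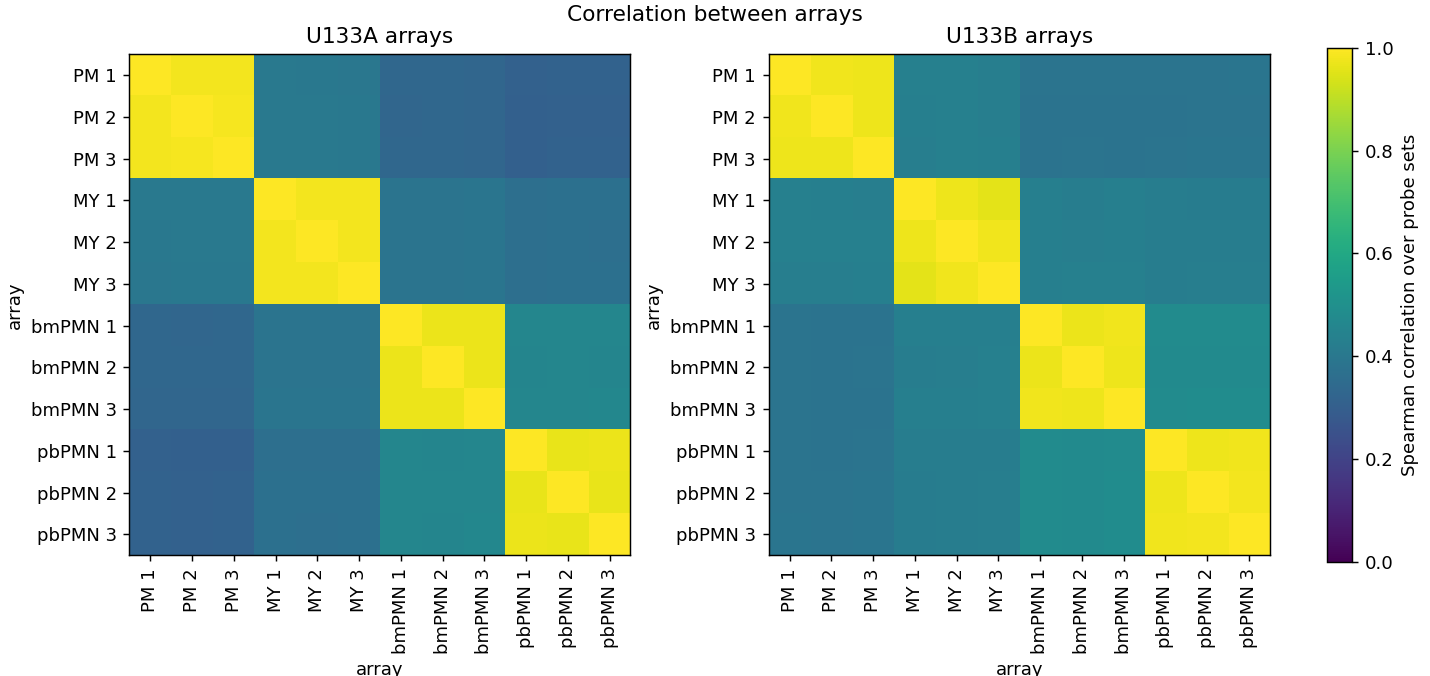
Spearman correlation over probe sets between all pairs of arrays of one type (colour scale 0 to 1, rows and columns labelled by population and replicate). The 4 blocks of replicates on the diagonal lie at 0.959 or above, and all pairs from different populations at 0.487 or below.

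Probe sets listed under the same gene did not resemble each other. Over 7108 pairs from 4310 genes on U133A and 5638 pairs from 3498 genes on U133B, Spearman correlations of level in the 4 populations ran from -0.018 to 0.027. For the log2 differences of the 4 comparisons they ran from -0.014 to 0.015. The smallest permutation p of these 16 correlations was 0.0441, with an adjusted p of 0.706. The 100 gene probe sets present on both array types correlated between -0.093 and 0.069 across the arrays (smallest permutation p 0.357). The 62 control probe sets present on both correlated between -0.154 and 0.012 (smallest permutation p 0.229). In the text below, a gene symbol therefore gives only the name under which a row is listed. Counts and tests of the gene lists likewise describe sets of rows. A list that was or was not called says nothing about the process or cell type it is named after.

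The following genes and rows were chosen after their values had been seen. The 21 rows listed under 8 genes that leukocytes express strongly (ACTB, GAPDH, B2M, EEF1A1, TPT1, FTL, S100A8 and S100A9) had a median percentile of intensity of 39.1 on U133A. Of their 84 values 9 lay above the 95th percentile, where 4.2 would by chance, and these came from 4 rows. One FTL row, under a ferritin chain, lay at percentiles of 95.4 to 98.7 in the 4 populations, and one S100A8 row at 98.1 to 99.0 in all but bmPMN, where it lay at 1.63. The 3 GAPDH rows had means from 16.7 to 35.6 in PM, 34.7 to 181 in MY, 40.02 to 89.3 in bmPMN and 56.9 to 123 in pbPMN. One B2M row read 1464 ± 288 (SD, n = 3) in MY and 46.5 ± 5.80 in PM, while the other read 78.9 ± 20.02 and 23.5 ± 6.23. The 78 rows listed under cytosolic ribosomal proteins had median percentiles of 51.4 in PM, 58.7 in MY, 49.3 in bmPMN and 51.9 in pbPMN. Over the 33 lists and 4 populations, 6 of 132 median percentiles fell outside the central 95% of random lists, where 6.6 would by chance. The 6 were specific granule proteins (69.4), glycolysis (68.1) and arachidonate metabolism (77.4) in MY, immediate early and stress genes (63.9) and marrow stroma and vessel wall markers (66.8) in PM, and B and plasma cell markers (33.8) in pbPMN.

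**Figure D2:**
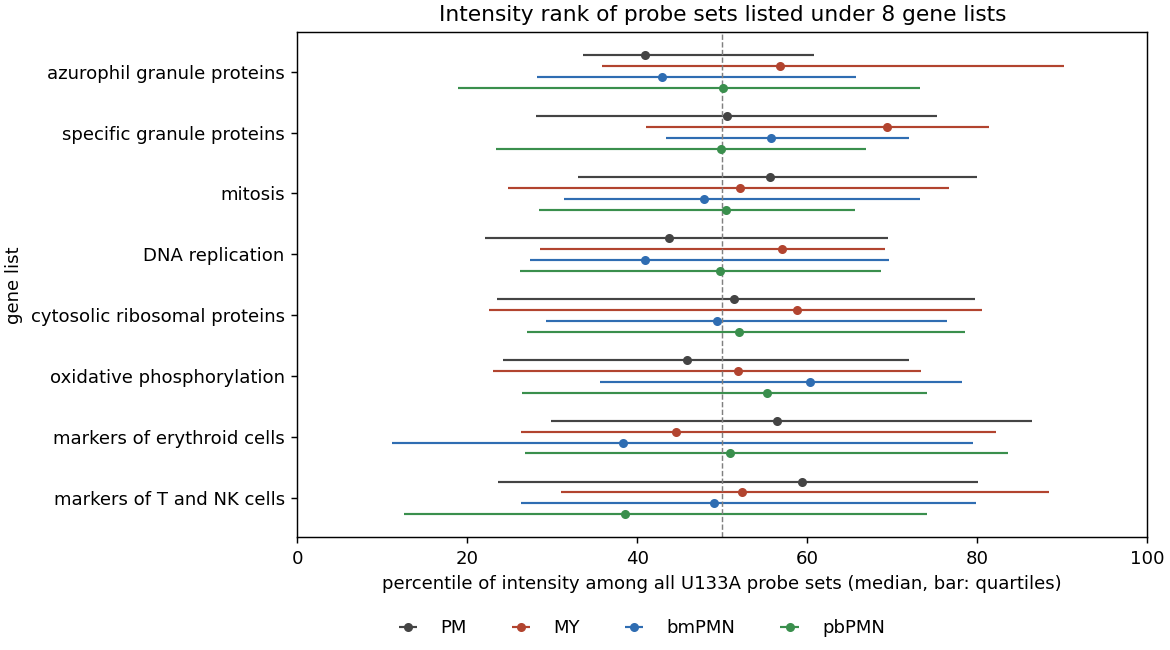
Median percentile of intensity among all U133A probe sets (x axis, 0 to 100; bars are quartiles) of the rows listed under 8 of the gene lists (y axis), in the 4 populations (colours). The medians lie between 38.4 (erythroid markers in bmPMN) and 69.4 (specific granule proteins in MY) around the dashed line at 50, and that of specific granule proteins in MY is the one outside the central 95% of random lists.

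Rows under granule protein genes, whose transcripts mark stages of the lineage, were examined in the 4 populations, with examples chosen after their values had been seen. One row listed under MPO, the myeloperoxidase of azurophil granules, read 264 ± 17.0 in PM, 201 ± 11.3 in MY, 130 ± 11.8 in bmPMN and 131 ± 28.1 in pbPMN, whereas the other MPO row read 24.3 ± 2.01, 102 ± 12.2, 6.76 ± 5.02 and 64.3 ± 6.34. The ELANE row, under neutrophil elastase, read 75.5 ± 34.8, 84.6 ± 29.7, 47.6 ± 8.74 and 40.1 ± 14.7 in the same order. Under LTF, the lactoferrin of specific granules, the values were 115 ± 10.9, 100.1 ± 17.0, 58.7 ± 8.78 and 506 ± 339. Under CXCR2, a chemokine receptor of mature neutrophils, they were 45.5 ± 3.24, 13.3 ± 8.58, 7.71 ± 6.28 and 11.5 ± 12.1. Under CAMP, the cathelicidin of specific granules, they were 511 ± 45.7, 171 ± 5.77, 59.0 ± 5.53 and 63.7 ± 11.2, and under FCGR3B, an Fc receptor of mature neutrophils, 150.5 ± 31.1, 2658 ± 245, 35.3 ± 5.15 and 2892 ± 189. The stage that MY stands for could not be checked from these rows.

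In MY against PM, rows listed under 5109 genes were higher and under 6326 lower in MY, 72.3% of the 15820 tested (limma, adjusted p under 0.05), and 7642 of them by more than 2-fold. The majority turned with scaling, to 5714 higher and 5289 lower after quantile normalization and 5567 and 5357 after median scaling. Rows named by the fixed rule as higher included ACOT8, a peroxisomal thioesterase, at 5789 ± 216 (SD, n = 3) in MY and 1 in each PM replicate, at least 298-fold (adjusted p = 5.69e-15). The PRSS3 row, under a trypsinogen, was 294-fold higher, at 6594 ± 617 against 22.4 ± 2.92. Among the falls, RPL41, a protein of the large ribosomal subunit, read 1.58 ± 0.623 in MY and 7844 ± 113 in PM, at least 403-fold lower (adjusted p = 4.29e-15). CCR9, a chemokine receptor, was at least 291-fold lower and S100A10, a member of the S100 protein family, at least 262-fold lower. Of 690 list members measured, 519 changed, or 75.2%. Rows under chemokines and cytokines rose in 5 and fell in 20 of 31 members (25 in all, 26 adjusted over the list alone), under apoptosis-promoting genes in 5 and 16 of 24 (21 adjusted over the list alone), and under mitosis genes in 5 and 13 of 26 (18). Examples are CXCL6, a neutrophil-attracting chemokine, at 2023 ± 239 in MY and 75.7 ± 10.95 in PM, and CYCS, cytochrome c, at 1.05 ± 0.0924 and 4096 ± 388. Azurophil granule rows rose in 4 and fell in 5 of 13 (9), ribosome biogenesis rows in 2 and 8 of 19 (9). After quantile normalization the chemokine and cytokine rows rose in 10 and fell in 15 of 29, with a median (log2) of -0.48 in place of -0.94, and the apoptosis-promoting rows in 8 and 14, with -0.43 in place of -0.77. The mitosis rows rose in 8 and fell in 8 after it, the azurophil rows in 6 and 3 and the ribosome biogenesis rows in 5 and 7, so the directions of these 3 lists turned or levelled with scaling. In tests of the lists against the remaining genes, camera called 0 of 33 lists, with a smallest unadjusted p of 0.0567 (adjusted p = 0.900), 0 lists under an unadjusted 0.05 and 0 called with an estimated correlation. fry called 26 on U133A, where the median log2 difference was -0.30 (0.23 on U133B, which fry did not use). Among them were the NADPH oxidase rows, of which 2 rose and 2 fell of 7 (fry adjusted p = 7.5e-06).

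In bmPMN against MY, rows listed under 4115 genes were higher and under 6910 lower in bmPMN, 69.7% of those tested, with 7407 over 2-fold. The share of higher calls, 37.3%, became 51.9% after quantile normalization and 53.5% after median scaling. The median log2 difference was -0.25 on U133A and -0.26 on U133B. NIPSNAP1, under a mitochondrial protein, read 6222 ± 166 in bmPMN and 2.89 ± 3.27 in MY, at least 320.0-fold higher (adjusted p = 1.32e-14), and GNAT3, the alpha subunit of gustducin, at least 213-fold higher. MFF, the mitochondrial fission factor, was at least 318-fold lower, at 4.39 ± 2.94 against 6179 ± 222 (adjusted p = 1.79e-14). IFNK, interferon kappa, was at least 260.4-fold lower. Of the list members, 484 changed, or 70.1%. Glycolysis rows rose in 2 and fell in 11 of 20 (13 adjusted over the list alone), specific granule rows in 3 and 12 of 22 (15), DNA replication rows in 7 and 15 of 26 (22), and apoptosis-opposing rows in 9 and 3 of 15 (12). Examples are ALDOC, an aldolase, at 4.12 ± 3.33 in bmPMN and 337 ± 15.5 in MY, and B2M, beta-2 microglobulin, at 23.3 ± 7.44 and 1464 ± 288. The other U133A row under B2M went the other way, at 183 ± 47.4 and 78.9 ± 20.02. The U133B row under B2M read 76.7 ± 30.3 and 88.5 ± 39.1. After quantile normalization the glycolysis rows rose in 4 and fell in 11 of 20 and the apoptosis-opposing rows in 9 and 2 of 14. The DNA replication rows rose in 10 and fell in 12 after it, and the specific granule rows in 3 and 9, with list medians (log2) of -0.19 and -0.093 in place of -0.60 and -0.51. camera called 0 of 33 lists (smallest unadjusted p 0.0685, adjusted p = 0.602; 0 under an unadjusted 0.05; 0 with an estimated correlation), and fry 25.

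In pbPMN against bmPMN, the neutrophils of blood and of marrow, rows listed under 4899 genes were higher and under 4104 lower in pbPMN, 56.9% of those tested, with 6369 over 2-fold. The majority turned with scaling, to 4413 higher and 4632 lower after quantile normalization and 4378 and 4768 after median scaling. This was the smallest count of the 4 comparisons. KCNN4, a calcium-activated potassium channel, read 5226 ± 320.5 in pbPMN and 8.61 ± 3.65 in bmPMN, at least 268-fold higher (adjusted p = 8.96e-15), and EIF5, a translation initiation factor, at least 231-fold higher. KIF26B, a kinesin family member, was at least 383-fold lower, at 16.2 ± 3.52 against 7454 ± 262 (adjusted p = 8.86e-15), and CDKN1C, a cyclin-dependent kinase inhibitor, at least 219-fold lower. Of the list members, 403 changed, or 58.4%. Haem synthesis rows rose in 0 and fell in 6 of 7 (7 adjusted over the list alone), and endoplasmic reticulum folding and secretion rows in 5 and 17 of 33 (22). Pattern recognition receptor rows rose in 13 and fell in 5 of 25 (18). After quantile normalization these 3 lists rose in 0, 5 and 11 and fell in 6, 18 and 6 members. Examples are ALAD, an enzyme of haem synthesis, at 1.52 ± 0.906 in pbPMN and 1632 ± 180.1 in bmPMN, and MYD88, an adaptor of Toll-like receptors, at 3856 ± 600.5 and 62.5 ± 3.275. These 3 lists had camera p under an unadjusted 0.05 (0.00632, 0.0174 and 0.0318), but none passed adjustment (0.209, 0.287 and 0.350), and with an estimated correlation the adjusted p were 0.827, 0.980 and 0.827. fry called 27 lists. The median log2 difference was 0 on U133A and 0.18 on U133B.

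In bmPMN against PM, rows listed under 4314 genes were higher and under 7580 lower in bmPMN, 75.2% of those tested, with 8530 over 2-fold. The share of higher calls, 36.3%, became 53.3% after quantile normalization and 53.4% after median scaling, and the median log2 difference was -0.59 on U133A and -0.02 on U133B. AKAP13, an anchoring protein of protein kinase A, read 7169 ± 1161 in bmPMN and 11.7 ± 1.83 in PM, at least 365-fold higher (adjusted p = 4.53e-14). MECOM, a zinc finger transcription factor, was at least 409.8-fold lower, at 6.22 ± 5.19 against 7967 ± 113 (adjusted p = 3.04e-15). Of the list members, 547 changed, or 79.3%. Stem cell and early progenitor marker rows rose in 3 and fell in 14 of 18, ribosomal protein rows in 8 and 22 of 36, and oxidative phosphorylation rows in 16 and 16 of 44 (17, 30 and 32 adjusted over the list alone). Examples are CD38, a surface enzyme, at 42.65 ± 11.3 in bmPMN and 1772 ± 136 in PM, and COX5B, a subunit of cytochrome c oxidase, at 2845 ± 178 and 9.97 ± 4.55. After quantile normalization the oxidative phosphorylation rows rose in 25 and fell in 13 of 46, the ribosomal protein rows in 14 and 17 of 37 and the stem cell marker rows in 3 and 8 of 17. The median of the stem cell marker list moved from -1.13 to -0.27, and to -0.10 after median scaling. camera called 0 of 33 lists (smallest unadjusted p 0.0493, adjusted p = 0.918; 1 under an unadjusted 0.05, oxidative phosphorylation; 0 with an estimated correlation), and fry 29.

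**Figure D3:**
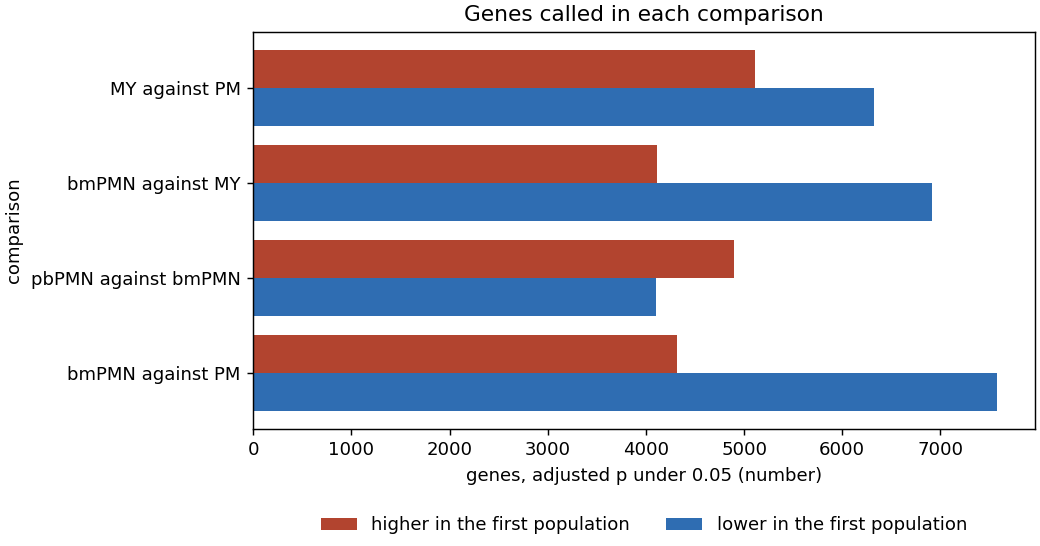
Number of genes (x axis) whose listed row was higher (red) or lower (blue) in the population written first, at an adjusted p under 0.05, in the 4 comparisons (y axis). The counts run from 4104 lower in pbPMN against bmPMN to 7580 lower in bmPMN against PM, and after quantile normalization or median scaling the majority direction turned in all 4.

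Among the named rows the dimmer population stood at the floor in 19 of 20 in MY against PM and 17 of 20 in bmPMN against MY. It did so in 16 of 20 in pbPMN against bmPMN and 8 of 10 in bmPMN against PM. The rule took the largest differences, so this follows largely from the choice of rows. Where the same gene had other probe sets on that array type, 7 of 19, 7 of 19, 10 of 26 and 6 of 11 of these went the same way. The rest include sets with no difference, both populations being at the floor. Of all these sets 12, 11, 18 and 2 differed by less than 2-fold in either direction.

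In MY against PM, erythroid marker rows rose in 3 and fell in 5 of 9, and T and NK cell rows in 4 and 10 of 18 (8 and 16 adjusted over the list alone). In pbPMN against bmPMN the erythroid rows rose in 3 and fell in 2, and the T and NK cell rows in 6 and 5 (5 and 11). The stem cell and early progenitor rows there rose in 10 and fell in 3 of 18 (14 adjusted over the list alone). In bmPMN against MY the marrow stroma and vessel wall rows rose in 2 and fell in 10 of 15 (12 adjusted over the list alone), and in 2 and 8 after quantile normalization. Other marker rows there, unnormalized, rose and fell in 1 and 2 of 9 (erythroid) and 6 and 9 of 18 (T and NK). B and plasma cell rows did so in 4 and 10 of 17, and eosinophil rows in 2 and 3 of 10. Monocyte, macrophage and dendritic cell rows did so in 5 and 9 of 16, and megakaryocyte and platelet rows in 3 and 6 of 10. Basophil and mast cell rows did so in 2 and 1 of 7, and stem cell and early progenitor rows in 3 and 11 of 18. In bmPMN against PM the rows that rose and fell were 4 and 5 of 9 for erythroid cells, 4 and 12 of 18 for T and NK cells, 4 and 9 of 17 for B and plasma cells and 5 and 9 of 16 for monocytes, macrophages and dendritic cells. They were 2 and 7 of 10 for megakaryocytes and platelets, 3 and 4 of 10 for eosinophils, 2 and 3 of 7 for basophils and mast cells and 3 and 10 of 15 for marrow stroma. The counts adjusted over each list alone were 9, 16, 13, 14, 9, 7, 5 and 13. After quantile normalization the rows that rose and fell in bmPMN against PM were, in the same order of lists, 4 and 4, 7 and 9, 5 and 9, 9 and 7, 3 and 5, 3 and 5, 3 and 1, and 5 and 8. The majority thus turned for monocytes, macrophages and dendritic cells and for basophils and mast cells, and the median (log2) of the marrow stroma list moved from -1.51 to -0.74. In MY against PM the normalized counts were 3 and 5 for erythroid and 6 and 9 for T and NK cell rows, and in pbPMN against bmPMN 3 and 2 and 5 and 5. The ratios of 3' to 5' control signal, a measure of RNA integrity where row names hold, differed between the populations and the array types. For GAPDH on U133A the ratio was 1.76 ± 0.284 (SD, n = 3) in PM, 0.106 ± 0.053 in MY, 1.71 ± 0.383 in bmPMN and 26.3 ± 11.6 in pbPMN, and for ACTB 2.81 ± 0.111, 13.1 ± 3.48, 5.76 ± 0.404 and 2.05 ± 0.083. On U133B the GAPDH ratio was 44.3 ± 6.16 in PM and 1.96 ± 0.178 in pbPMN, and the ACTB ratio 0.0139 ± 0.00218 and 0.0678 ± 0.00944. Since probe sets of the same gene did not resemble each other, these ratios were not read as RNA integrity.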

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

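Of the tests in this part, all but that of overall scaling were chosen or worded after the result was seen. Control probe sets lie outside the comparisons, and 3 of their 124 rows with values stood above the 95th percentile on all 12 arrays of their type. On U133A the cre control CreX-3 had a median intensity of 2034 (1606 to 2971) and CreX-5 one of 4528 (3815 to 6328), but their medians on U133B were 62.1 and 22.5. The other cre rows, r2-P1-cre-3 and r2-P1-cre-5, had medians of 77.6 and 194.7 on U133A and 45.1 and 66.3 on U133B. On U133B the 5' row of the ACTB control had a median of 1424 (1271 to 2650).

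The row names did not carry gene identity. A table moved by a constant number of rows, or sorted by one of the other keys tried, does not account for this. Over all cyclic shifts of 12 orders the highest correlation within genes was 0.0619, against 0.0570 in shuffled rows. The latter is the highest of only 3 shuffles per population, so the 2 values come from unlike numbers of scans. A simulated shift on U133A with a correlation of 0.3 within genes was recovered at 0.309. Weaker agreement and orders that were not tried stay open. A misplacement in some populations alone is also argued against, since the highest correlation in a population was 0.0268. A candidate explanation that stays open is a signal summarised over features of the array that do not belong to the probe set. Of rows over 10 on the log2 scale in one population, 53.4% were brighter or less than 2-fold lower in another. Another 30.6% were over 16-fold lower, and 15.97% lay in between. The share in between was 2.62% to 11.9% on U133B and 16.6% to 34.9% on U133A, which leaves this explanation open. No biological explanation was tested.

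In all 4 populations 328 U133B rows lay between 2048 and 5793, and 37 did on U133A. Whether a common source of signal lies behind those of U133B could not be decided. On U133B the median correlation of such a row with the mean of the others over 12 arrays was 0.689, against 0.453 for 219 dimmer rows, a value between the limits set for either answer, and no biological explanation was tested. On U133A it was 0.421, against 0.238 for 290 dimmer rows. The values were not scaled between arrays. The 328 U133B rows had medians of 2754 in PM, 3248 in MY, 2591 in bmPMN and 3267 in pbPMN. The whole U133B arrays had median intensities in the same rank order (50.3, 57.1, 46.8 and 58.5). Array-wide scaling could thus give a shared profile by itself, so these correlations cannot decide on a common source.

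In each of the 4 comparisons most of the genes tested differed. Among U133B rows above the floor in both populations, 54.7% to 65.5% were within 1.5-fold in 5 of the 6 pairs. The share was 49.7% in PM and pbPMN, and 30.3% to 52.1% on U133A. With shuffled rows it was 21.8% to 24.2%. These shares leave out rows at the floor in either population and count every probe set, not 1 per gene. Different overall scaling does not account for the number of genes that differed, as quantile normalization left at least 96.2% of the count in each comparison. It did turn the majority direction. The splits of 6 samples, 10 per comparison, are too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes (11435, 11025, 9003 and 11894), and the highest of the others gave 0. Every other split puts arrays of both populations in each group, so the spread within its groups holds the difference between the populations. A count near 0 follows from this and adds no evidence. A difference between the populations themselves stays open and untested, as does a population-specific step in making the tables.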

How the results depend on the processing

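The counts of genes changed stayed within 1.5 times under all alternatives but a minimum fold. Against a 2-fold change limma's treat called 5964 genes in MY against PM, 5855 in bmPMN against MY, 5082 in pbPMN against bmPMN and 6919 in bmPMN against PM, by construction fewer. Leaving out 1 replicate gave 10983 to 11147, 10479 to 10673, 8657 to 8845 and 11508 to 11626 genes. The count of lists shifted by camera was 0 with an estimated correlation, quantile normalization, no filter, the block and each replicate left out. With the replicate number as a block the counts were 11537, 11099, 9067 and 11982. Deviations of same-numbered samples correlated by 0.060 on average on either array type, over 0.1 in 3 of 18 pairs on U133A and 7 of 18 on U133B, and those of different-numbered samples by -0.030 and -0.029, over 0.1 in 0 of 36 and 2 of 36. As not all same-numbered pairs were over 0.1, the numbers were not taken as pairs. True pairs could also miss this bar, so pairing stays open. As a hint from the data and not the design, each of the 12 samples correlated best with a sample of its own number on U133A, and 8 of 12 did on U133B.

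Of 1310 values of named rows under alternatives, 1297 kept direction and call, 11 lost the call, 6 of them with a change of sign, and 2 (MRPS23 and DIAPH2) were called in the other direction. In all 13 another probe set was taken for the gene. The named rows had been picked for the largest differences in these data, so refits that kept the probe set could hardly change a call. Rows absent under an alternative were not counted. With the floor at the 5th percentile the log2 difference was -0.15 under CPEB2 and 1.28 under MRPS23 in MY against PM, -0.14 under WDR48 in bmPMN against MY and -0.20 under VPS13D in pbPMN against bmPMN. Without _s_at and _x_at probe sets it was -0.042 under CMBL in MY against PM, -2.44 under DIAPH2 and -0.14 under WDR48 in bmPMN against MY, and 0.29 under SPARC in pbPMN against bmPMN.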
